A study of Mus musculus with 4 samples.

How the data were processed

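Total RNA was depleted of ribosomal RNA and made into libraries with a kit that, per the labels' protocols, was not named as a strand-marking one, so reads of overlapping or antisense genes could not be told apart. The series held 4 libraries, 2 of ADRCs and 2 of GFP-positive cells collected 3 weeks after transduction with 6 factors. The genome build was GRCm38, per the submitters' processing notes, and the aligner and the counting tool were not given in the sources used here.

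The authors deposited 1 table of 50600 genes. Per the file headers it holds, for each library, total exon reads, which are whole-number counts and were used here as deposited. The deposited table also holds the authors' group means in RPKM (reads scaled by exon length and mapped reads), and a signal made by the authors from those RPKM by normalization across libraries, likewise as group means. The authors' comparison, named EDGE in the file headers, gives a fold change, a p-value and a false discovery rate per gene, and the values it was computed from are not given in the sources used here. The table held 52 further columns of per-sample values, 13 per library, which were not used here. Column names carried the group but no replicate number, so the libraries of a group are called a and b without order.

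Exon length was 0 for 18045 genes, which had 0 exon reads and were left out, leaving 32555. Gene IDs were matched to GENCODE M21 on GRCm38, where 99.6% were found. Of the matched genes, 93.0% had a deposited start 1 lower than in GENCODE and the same end, and 94.2% the same symbol. Positions are given 1-based from GENCODE. Mapped reads per library were recovered by solving the authors' group mean RPKM for the 2 library totals. The authors' RPKM divide by all mapped reads: over the 12392 tested genes with values above 0, the median log2 ratio of the authors' mean RPKM was 2.26, that of their normalized signal -0.05, and that of the fit used here 0.07 over all tested genes.

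Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr, libraries were scaled by TMM, and groups were compared with the quasi-likelihood test, with Benjamini-Hochberg adjustment over the 12573 genes tested and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of the quasi-likelihood F. CPM were computed by edgeR on TMM-scaled library sizes and are given as mean and SD of 2 libraries. Where a group had 0 reads in both libraries a fold was computed against a floor of 3 reads over the group, 0.660 CPM for ADRCs and 0.191 CPM for 6F cells. With 1 to 3 reads in a group, the pooled ratio is given with its 95% exact (Clopper-Pearson) interval.

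Before the data were examined, 34 gene lists were written and tested with camera at a preset correlation of 0.01, with adjustment over the lists. With a correlation estimated from these 4 libraries, 0 of the 34 lists passed the threshold, against 14 with the preset one, and 7 had an unadjusted p under 0.05. That setting also limits camera to the residual degrees of freedom of the 4 libraries, so a lost call need not come from correlation between genes. The lists of candidate introduced factors and of cardiac transcription factors share genes. The rule for the genes named was also written then. It takes the candidate introduced factors and Myh6, the first 10 rises and first 10 falls by fitted log2 fold change among called protein-coding genes with non-overlapping libraries and at least 10 CPM in the higher group, up to 4 called members of each list by size of change, and up to 2 members not called as values. It gave 194 genes, of which 136 were called. The 98 of these that the texts name, 90 of them called, were picked after their values were seen, and 1 gene is not reported here.

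The alternatives were DESeq2 size factors, scaling by library size, no low-count filter, a mean of at least 1 CPM, the DESeq2 1.42.0 Wald test, leaving out each library, a 2-fold threshold and the estimated correlation of camera. Added after seeing the data were leaving out the 3 genes that collect ribosomal reads (Rn18s-rs5, Gm26917 and Lars2), thinning the 6F libraries to 2468012 exon reads, and loess offsets on exon length and GC content with a span of 0.3, for which 99.9% of tested genes had a GC value. The edgeR procedure was tested on simulated data for this comparison, with counts drawn for the real genes from the ADRC means, the real library sizes and 200 changed genes. Of 50 genes changed at each size, it recovered 4 at 1.5-fold, 15 at 2-fold, 44 at 4-fold and 50 at 8-fold, and called 11 of 11285 unchanged genes, among 11485 tested. The simulation changed few genes, with rises and falls balanced, and gave both groups the same dispersion. Its changed genes were drawn only from those above a minimum CPM in ADRCs. The recovery therefore does not cover genes with few ADRC reads, such as the 459 higher genes with 3 or fewer. In the data 5908 genes were called, and the median absolute log2 difference between libraries was 0.183 for ADRCs and 0.306 for 6F cells. The simulated rate of false calls therefore need not hold for these data. No statement here rests on a change of under 2-fold being absent.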

Results

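RNA was measured in adipose-derived regenerative cells (ADRCs), the mesenchymal cells grown out of mouse inguinal and axillary fat, and in ADRCs that had received 6 transcriptional factors. The untreated group held 2 libraries of passage 2 cells from C57BL/6J mice at 8 weeks of age. The treated group held 2 libraries of cells collected 3 weeks after transduction by fluorescence-activated sorting for GFP, from a strain in which the promoter of Myh6, the cardiac alpha myosin heavy chain, drives GFP. The groups therefore differed in transduction, time in culture and sorting together, and in strain by the strain labels. The titles of the ADRC libraries call them a positive control for the reporter, which is at odds with their strain label, so whether the strain differed is not settled here. Exon reads per library came to 2273897 and 2662128 in the ADRC libraries a and b, and to 7593772 and 6986223 in the sorted 6-factor (6F) libraries a and b. Exon reads made up 14.2% and 16.1% of the mapped reads in the ADRC libraries, against 60.2% and 59.6% in the 6F libraries. The groups thus also differed in depth and library composition, so effects of RNA or library preparation cannot be told apart from the other differences. Intervals and floors given here cover counting error only. The labels do not say that the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

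The comparison asked how the transcriptome of the sorted 6F cells differed from that of untreated ADRCs. Of 20 tested cardiac sarcomere genes 13 rose, of 20 smooth muscle genes 14 rose, and of 32 cell cycle genes 31 fell in the 6F cells (camera adjusted p = 0.139 with an estimated correlation for each of these lists). Myh6 stood at 4.39 ± 0.0836 CPM (CPM, exon read counts scaled by TMM-adjusted library size; SD, n = 2) in ADRCs and at 1208 ± 478 CPM in 6F cells, and Myh11, the smooth muscle myosin heavy chain, at 28.9 ± 2.06 against 3002 ± 90.1 CPM. Plk1, a mitotic kinase, went the other way, from 110 ± 0.497 to 2.53 ± 0.351 CPM. Of 12573 genes tested with edgeR's quasi-likelihood test, 3038 were higher and 2870 lower in 6F cells at a Benjamini-Hochberg adjusted p under 0.05, and 2339 and 1815 of these changed at least 2-fold. All 5908 called genes had libraries that did not overlap between the groups. Selection on these same libraries nearly forces this, so it adds no support. Chance gives 33.3% of genes such non-overlap with 2 libraries against 2, and the share over all tested genes is not given here. Log2 CPM correlated across genes at 0.977 between the ADRC libraries, 0.954 between the 6F libraries and 0.725 to 0.766 between groups. Measured against counting error, the chi-square per gene was 1.99 between the ADRC libraries and 35.1 between the 6F libraries. That value also grows with depth, which was higher in the 6F libraries. The test fitted a single dispersion per gene over both groups, so its p-values pool unlike spreads. Scaling by library size alone gave 3920 higher and 2128 lower genes and moved the median log2 fold change of all tested genes from 0.07 to 0.30. Without ADRC library a, 1258 genes were higher and 1204 lower, and without ADRC library b, 1220 and 1165.

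The 6 candidate introduced factors were all higher in the 6F cells. The labels do not name the factors, and this list was written from knowledge of the study. Exon reads do not separate an introduced coding sequence from the cell's own transcript. Gata4, a zinc finger factor of heart development (ENSMUSG00000021944; GRCm38 chromosome 14, 63198922 to 63271692), had 0 and 2 reads in the ADRC libraries and 5408 and 1917 in the 6F libraries, a pooled ratio of 1058 with a 95% exact counting interval of 293 to 8742. The Gata4 ratio was 575 without ADRC library a, 585 without 6F library a and 1480 without 6F library b, and without ADRC library b, which held both reads, Gata4 was at least 322-fold higher. Myocd, the coactivator of serum response factor (ENSMUSG00000020542; chromosome 11, 65176561 to 65269989), rose by a log2 fold change of 9.13 ± 0.71 (SE), from 4.27 ± 1.46 to 2373 ± 1622 CPM. Klf15, a Kruppel-like factor (ENSMUSG00000030087; chromosome 6, 90462576 to 90475238), rose by 6.85 ± 0.30 on the log2 scale. Smarcd3, a subunit of the SWI/SNF chromatin remodelling complex (ENSMUSG00000028949; chromosome 5, 24590818 to 24624411), rose by 5.10 ± 0.48, and Gata6 (ENSMUSG00000005836; chromosome 18, 11052064 to 11085635) by 4.80 ± 0.24. Mef2a, a MADS box factor (ENSMUSG00000030557; chromosome 7, 67231163 to 67372858), had the smallest rise of the 6, 1.85 ± 0.31, from 75.4 ± 4.27 to 272.6 ± 119 CPM. The edgeR adjusted p of the 6 genes lay between 0.000109 for Klf15 and 0.00451 for Mef2a, and all 6 were also called when adjusted over the list alone. Their median log2 fold change was 5.98 (camera adjusted p = 2.98e-11), and the call was lost with an adjusted p = 0.427 with an estimated correlation. If these are the factors introduced, their rise was built into the experiment, so the list test is a check of the design and no finding. The size of the rise varied with the 6F library used: the Myocd log2 fold change was 8.20 without 6F library a and 9.74 without 6F library b, that of Mef2a 1.33 and 2.28, and that of Smarcd3 4.31 and 5.64.

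**Figure D1:**
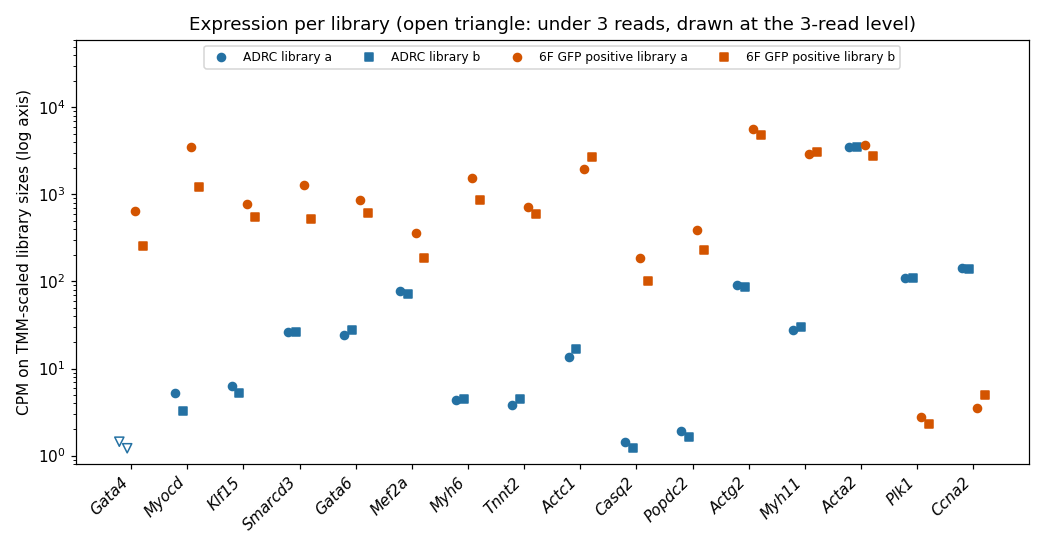
CPM on TMM-scaled library sizes (log axis) of the candidate introduced factors and of named muscle and cell cycle genes, with 1 point per library, circles for library a and squares for library b. Both 6F libraries lie above both ADRC libraries for Myh6 (1208 against 4.39 CPM on average) and below them for Plk1 (2.53 against 110 CPM), whereas the groups overlap for Acta2.

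Sarcomere genes rose in part. Of 20 tested members of the cardiac sarcomere list, 13 were higher, 0 lower and 7 not past the threshold (14 higher when adjusted over the list alone), with a median log2 fold change of 3.23 (camera adjusted p = 4.32e-13; adjusted p = 0.139 with an estimated correlation) that was 3.98 without 6F library b. The sarcomere median was 1.24 with the DESeq2 test and 2.23 with no low-count filter, each over 29 genes, and 4.17 over the 15 genes tested with thinned 6F libraries. Myh6 (ENSMUSG00000040752; chromosome 14, 54941921 to 54966927) rose by 8.10 ± 0.41 (SE) on the log2 scale (edgeR adjusted p = 0.000111). This gene's promoter drives the reporter by which the cells were sorted. Tnnt2, cardiac troponin T, rose by 7.29 ± 0.24, from 4.15 ± 0.424 to 656.7 ± 75.2 CPM, and Actc1, cardiac alpha actin, by 7.28 ± 0.29, from 15.03 ± 2.20 to 2345 ± 518 CPM. Smpx, a small muscle protein, had 1 read over both ADRC libraries, and its pooled ratio was 178 with an interval of 31.8 to 7043. The ratio was 96.7 without ADRC library a, and Smpx was at least 27.1-fold higher without ADRC library b. Tpm1, a tropomyosin, stood at 1215 ± 32.3 and 1569 ± 144 CPM, and Myh7, the beta myosin heavy chain, at 9.32 ± 5.70 and 11.3 ± 3.54 CPM, with edgeR adjusted p of 0.109 and 0.687. The other 10 members of the list had too few reads to be tested.

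Genes of calcium handling and ion channels rose in part. Of 17 tested members, 11 were higher, 0 lower and 6 not past the threshold (12 higher when adjusted over the list alone), and 12 members had too few reads to test. The median log2 fold change was 2.73, also with the 2 members without ADRC reads set at their bound (camera adjusted p = 6.62e-06; adjusted p = 0.198 with an estimated correlation), and the median was 3.40 without ADRC library b and 3.35 with thinned 6F libraries. Leaving out 6F library a or b gave 1 or 2 lower members. Casq2, the calcium store protein calsequestrin, rose from 1.33 ± 0.163 to 144.7 ± 61.6 CPM. Cacna1h, a T-type calcium channel, and Kcnq1, a potassium channel, had 0 reads in both ADRC libraries and were at least 26.2-fold and 15.4-fold higher in 6F cells against a floor of 3 reads over the group. The 6F libraries a and b had 66 and 206 Cacna1h reads, so that the bound was 41.9-fold without 6F library a and 12.1-fold without 6F library b. For Kcnq1 they had 108 and 52 reads, with bounds of 10.6-fold and 19.8-fold. Gja1, a gap junction protein, stood at 104.8 ± 2.90 and 85.7 ± 39.5 CPM (edgeR adjusted p = 0.472).

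Of 17 tested natriuretic peptide and other cardiomyocyte genes, 13 were higher, 0 lower and 4 not past the threshold (13 when adjusted over the list alone, 8 higher without ADRC library b), with a median of 3.03 (camera adjusted p = 3.39e-08; adjusted p = 0.167 with an estimated correlation). Popdc2, a membrane protein of striated muscle, rose from 1.77 ± 0.217 to 310.5 ± 115 CPM, and Dmd, dystrophin, from 8.23 ± 2.10 to 264.2 ± 38.4 CPM. Bves, a relative of Popdc2, had 2 ADRC reads in all and a pooled ratio of 141 with an interval of 39.0 to 1167. Its ratio was 76.7 without ADRC library a and 86.9 without 6F library a, and it was at least 43.0-fold higher without ADRC library b. Hspb6, a small heat shock protein of muscle, rose by 3.98 ± 0.40 on the log2 scale. Among the cardiac transcription factors, 8 of 18 tested were higher, 3 lower and 7 not past the threshold (9 and 3 when adjusted over the list alone), with a median of 1.36 (camera adjusted p = 0.000177; adjusted p = 0.233 with an estimated correlation). All 6 candidate introduced factors are members of that list and are among its 8 higher genes, so its test is not independent of their introduction. The other higher members, Mef2c and Hopx, and the lower ones, Tbx18, Zfpm2 and Nr2f2, were picked out after their values were seen. Neither Mef2c nor Hopx was called without ADRC library b, and Hopx had 1 read in each ADRC library. Scaling by library size alone gave 9 higher and 0 lower members of the list, and leaving out ADRC library a or b left 0 lower. The list's median was 0.69 with the DESeq2 test and 0.76 with thinned 6F libraries. Nkx2-5, Hand1 and Irx4, cardiac transcription factors chosen after their values were seen, had 0 reads in all 4 libraries, which allows up to 0.191 CPM over the 6F group.

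Most tested smooth muscle genes were higher as well. Of 20 tested members, 14 were higher, 0 lower and 6 not past the threshold (15 higher when adjusted over the list alone), with a median of 2.21 (camera adjusted p = 3.97e-16; adjusted p = 0.139 with an estimated correlation), and 1 or 2 were lower without 6F library a or b. Actg2, the gamma smooth muscle actin, rose from 89.2 ± 2.54 to 5294 ± 584 CPM, and Mylk, the myosin light chain kinase, from 43.6 ± 4.41 to 2567 ± 642 CPM. Myh11 rose by 6.70 ± 0.21 on the log2 scale, and Kcnmb1, a subunit of a potassium channel, had 1 ADRC read and a pooled ratio of 473 with an interval of 84.8 to 18710. The Kcnmb1 ratio was 216 without ADRC library b, and the gene was at least 85.7-fold higher without ADRC library a. Acta2, the alpha smooth muscle actin, was already abundant in ADRCs at 3497 ± 27.2 CPM, against 3225 ± 619 CPM in 6F cells, and Cald1, caldesmon, stood at 1384 ± 70.7 and 1322 ± 323 CPM, and both changed sign with scaling by library size alone (edgeR adjusted p = 0.66 and 0.814). Of 7 tested skeletal muscle genes, 4 were higher and 2 lower (5 and 2 when adjusted over the list alone), and the list was not past the threshold (camera adjusted p = 0.11), which it passed without 6F library b (median 3.98, adjusted p = 0.000269). Acta1, the skeletal alpha actin, rose from 22.1 ± 1.46 to 1665 ± 1116 CPM, with a log2 fold change of 5.32 without 6F library a and 6.83 without 6F library b, and Tnnt1 and Cacna1s rose by 4.50 ± 0.44 and 5.47 ± 0.41 on the log2 scale. Myh3, the embryonic myosin heavy chain, had 33 and 19 ADRC reads and 0 in 6F cells, at least 60.0-fold lower against the 3-read floor over the group. That bound was 40.3-fold and 83.3-fold without ADRC library a and b, and 28.4-fold and 31.6-fold without 6F library a and b, where the floor rests on 1 library.

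**Figure D2:**
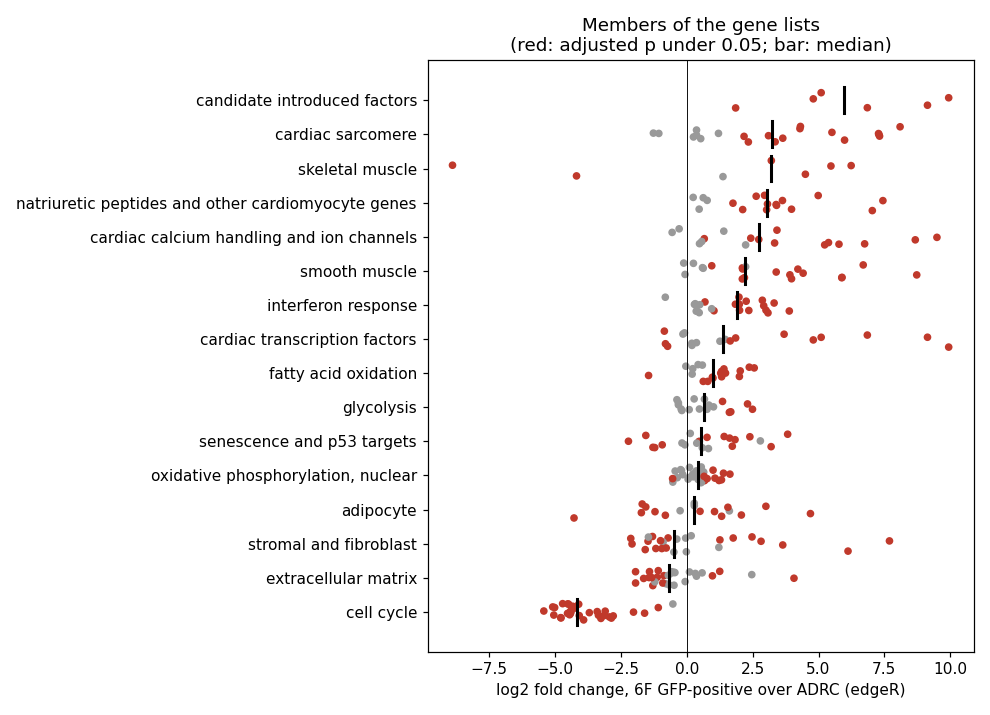
Log2 fold change of 6F over ADRC cells (edgeR) for each tested member of the primary gene lists, red where the adjusted p was under 0.05 and grey otherwise, with a bar at the list's median. The medians run from -4.17 for cell cycle genes to 5.98 for the candidate introduced factors, with sarcomere genes at 3.23 and smooth muscle genes at 2.21.

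Genes of cell division fell together. Of 32 tested cell cycle genes, 31 were lower, 0 higher and 1 not past the threshold, also when adjusted over the list alone, and the median log2 fold change was -4.17 (camera adjusted p = 2.36e-53; adjusted p = 0.139 with an estimated correlation). Plk1 fell by 5.43 ± 0.21 (SE) on the log2 scale, Birc5, which encodes survivin, by 5.09 ± 0.28, Ccna2, a cyclin of S phase and mitosis, by 5.05 ± 0.23, and Aurkb, a mitotic kinase, by 5.02 ± 0.32 (edgeR adjusted p of 0.000109, 0.000129, 0.000109 and 0.000189). E2f1, a transcription factor of S phase entry, stood at 32.1 ± 3.84 and 22.3 ± 6.78 CPM (edgeR adjusted p = 0.154). Of 10 tested replication-dependent histone genes, 8 were lower, 0 higher and 2 not past the threshold, with a median of -3.12 (camera adjusted p = 1.26e-12; adjusted p = 0.139 with an estimated correlation). Among senescence genes and p53 targets, 9 of 22 were higher and 5 lower (11 and 5 when adjusted over the list alone), and the list was not past the threshold (camera adjusted p = 0.113). Leaving out ADRC library a or b left 4 higher and 2 lower. Cdkn2a, a cell cycle inhibitor locus, had 3 and 13 ADRC reads and rose by 3.83 ± 0.59 on the log2 scale, and Trp53inp1, a p53 target, rose by 3.20 ± 0.21. The log2 fold change of Cdkn2a was 3.21 without ADRC library a, 5.06 without ADRC library b and 3.19 without 6F library a.

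Stromal, matrix and adipocyte genes moved in both directions. Of 25 tested stromal and fibroblast genes, 7 were higher and 10 lower (8 and 11 when adjusted over the list alone), with a median of -0.49 and a mean of 0.43, so that the median and the mean differed in sign (camera adjusted p = 0.705, direction down). The stromal median was -0.63 without 6F library b and -0.14 without 6F library a, and -0.44 and -0.59 without ADRC library a and b. The list passed the threshold only without 6F library b. Lum, a proteoglycan of collagen fibres, rose from 2.18 ± 0.355 to 27.7 ± 10.7 CPM, and Gli1, a transcription factor of hedgehog signalling, had 1 ADRC read and a pooled ratio of 77.2 with an interval of 13.7 to 3059. That ratio was 41.9 without ADRC library a, and Gli1 was at least 11.7-fold higher without ADRC library b. Of 29 extracellular matrix genes, 3 were higher and 11 lower (the same numbers when adjusted over the list alone), with a median of -0.67 that missed the threshold (camera adjusted p = 0.0553). The matrix median was -0.60 and -0.75 without ADRC library a and b, and -0.37 and -1.06 without 6F library a and b. The matrix list passed the threshold in each of these fits but the one without 6F library a. Ctgf and Thbs2, matrix-associated proteins, fell by 1.95 ± 0.21 and 1.94 ± 0.20 on the log2 scale, whereas Mmp3, a matrix metalloproteinase, rose by 4.07 ± 0.48, or 3.40 without 6F library a. Col6a2, a collagen VI chain, fell by 1.64 ± 0.33, a call lost without ADRC library a (log2 fold change -1.58, edgeR adjusted p = 0.0579). Of 17 adipocyte genes, 7 were higher and 6 lower (8 and 6 when adjusted over the list alone), with a median of 0.28 against a camera direction of down (adjusted p = 0.98), and with 1 higher and 2 lower without ADRC library a, or 2 and 3 without ADRC library b. The adipocyte median was 1.11 with no low-count filter and 1.06 with the DESeq2 test, and the camera direction was up in both. Slc2a4, the insulin-responsive glucose transporter, rose from 0.924 ± 0.735 to 23.5 ± 1.31 CPM, and Cd36, a fatty acid transporter, fell from 83.7 ± 26.4 to 4.27 ± 1.48 CPM. The log2 fold change of Slc2a4, from 3 and 1 ADRC reads, was 5.76 without ADRC library a and 3.98 without ADRC library b.

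Most tested genes of fatty acid oxidation were higher, and the lists of nuclear oxidative phosphorylation genes and of glycolysis genes passed the threshold with some settings and not with others. Of 19 tested fatty acid oxidation genes, 13 were higher and 1 lower (14 and 1 when adjusted over the list alone), with a median of 0.99 (camera adjusted p = 0.0023; adjusted p = 0.659 with an estimated correlation), and 6 and 4 were higher without ADRC library a and b. Etfdh, which passes electrons from beta-oxidation to the respiratory chain, rose by 2.37 ± 0.20 on the log2 scale, Pdk4, an inhibitory kinase of pyruvate dehydrogenase, by 2.03 ± 0.23, and Acaa2, a thiolase, by 2.00 ± 0.19. Of 33 nuclear genes of oxidative phosphorylation, 9 were higher and 1 lower (8 and 1 when adjusted over the list alone; camera adjusted p = 0.0974), or 20 and 0 with scaling by library size alone. Without ADRC library a or b 3 or 2 were higher, without 6F library a 16 were higher and 8 lower, and without 6F library b the list passed the threshold with 26 higher and 2 lower (adjusted p = 0.00273). Cox7a2, a subunit of cytochrome oxidase, rose by 1.64 ± 0.21. Cox4i1, another subunit, rose by 1.22 ± 0.19, a call lost without ADRC library a (1.14, edgeR adjusted p = 0.0757) or b (1.26, adjusted p = 0.0608). Of 17 glycolysis genes, 5 were higher and 0 lower, also when adjusted over the list alone (camera adjusted p = 0.15). The glycolysis list passed without 6F library a, with 15 higher (median 1.14, adjusted p = 6.64e-07), and had 6 higher and 7 lower without 6F library b and 1 higher without 1 of the ADRC libraries, whichever was left out. Pfkm, the muscle phosphofructokinase, rose from 24.1 ± 1.39 to 118.8 ± 18.1 CPM. Pgk1, phosphoglycerate kinase, rose by 1.62 ± 0.31, a call lost without ADRC library a (1.57, edgeR adjusted p = 0.0772) or b (1.61, adjusted p = 0.0722). Interferon response genes were higher, 14 of 22 with 0 lower (15 when adjusted over the list alone) and a median of 1.91 (camera adjusted p = 0.0023; adjusted p = 0.51 with an estimated correlation). The interferon count was 5 and 7 higher without ADRC library a and b, and the median was 1.14 without 6F library a, with 13 higher and 1 lower. Ifit3, an interferon-induced protein, rose by 3.31 ± 0.51, or 2.72 without 6F library a. Gbp3, an interferon-induced GTPase, had 1 and 4 ADRC reads and rose by 3.01 ± 0.57, a call lost without ADRC library a (2.42, edgeR adjusted p = 0.0549) and at 4.13 without ADRC library b.

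Ranked by fitted log2 fold change, the first 10 rises among protein-coding genes with at least 10 CPM were of genes without a read in either ADRC library. Their fitted values depend on the prior count, and their bounds lie below the pooled ratio of 1058 for Gata4, so this order does not establish them as the largest rises. Hs3st6, a heparan sulfate sulfotransferase, had 1862 and 702 reads in the 6F libraries and was at least 247-fold higher, and Prnd, a relative of the prion protein, was at least 183-fold higher, each against a floor of 3 reads over the ADRC group. BC030499, Slc25a34, A630076J17Rik, Cyp4f14, Calcoco2, Phyhip, Prl7b1 and Ccna1 were at least 60.3-fold to 110-fold higher against the same floor. Without 6F library a the bound was 143-fold for Hs3st6, 21.8-fold for Calcoco2 (108-fold without 6F library b), 37.6-fold for Prl7b1 and 30.1-fold for Ccna1. In all, 173 of the 3038 higher genes had no ADRC read and 459 had 3 or fewer. Of the first 10 falls in the same ranking, 7 were histone genes (Hist1h2ai, Hist1h2ah, Hist1h4m, Hist1h3g, Hist1h3d, Hist1h3b and Hist1h2an), whose near-identical copies share reads, so that the value of each single gene is uncertain. The others were Myh3, Slc38a4, an amino acid transporter that fell by 6.23 ± 0.36 on the log2 scale, and Mmp12, the macrophage metalloelastase, which fell from 189 ± 8.88 to 2.68 ± 3.61 CPM. The log2 fold change of Mmp12 was -5.16 without 6F library a and -10.27 without 6F library b, and that of Hist1h4m -7.10 and -11.67. In 6F library a Mmp12 had 1 read and Hist1h4m 0, so the values without 6F library b depend on the prior count and their size is uncertain.

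Markers of other cell types gave mixed counts. Of 16 tested macrophage and myeloid genes, 7 were lower and 0 higher, also when adjusted over the list alone, with a median of -2.27 (camera adjusted p = 0.0181; adjusted p = 0.793 with an estimated correlation). The median of the macrophage list was -1.35 without 6F library a and -7.01 without 6F library b, with 12 and 14 lower and 1 higher in each, and 3 and 1 were lower without ADRC library a and b. Cd68, a lysosomal protein of macrophages, fell from 41.2 ± 1.00 to 3.21 ± 2.49 CPM, with a log2 fold change of -3.03 without 6F library a and -4.77 without 6F library b. Tyrobp, a myeloid signalling adaptor, fell by 4.31 ± 0.97, a call lost without ADRC library b (-4.05, edgeR adjusted p = 0.0834) and with DESeq2 (-4.32, adjusted p = 0.111), and stood at -3.28 and -8.96 without 6F library a and b. Tyrobp and some other members had 0 reads in 6F library a, where a fitted value depends on the prior count. The size of the values without 6F library b, -8.96 for Tyrobp and -7.01 for the list, is therefore uncertain. Lyz2, lysozyme, had 347 and 421 ADRC reads and 34 and 609 reads in the 6F libraries a and b (edgeR adjusted p = 0.158). Of 8 endothelial genes 2 were higher and 2 lower (camera adjusted p = 0.93), against 1 and 0 with ADRC library a or b left out. Esam, an endothelial adhesion molecule, rose by 4.31 ± 0.41 on the log2 scale. Pecam1, another endothelial adhesion molecule, fell by 3.62 ± 0.76, a call lost without ADRC library a (-3.93, edgeR adjusted p = 0.0654), with -2.84 and -5.05 without 6F library a and b. Of 8 pericyte genes 4 were higher and 1 lower (camera adjusted p = 0.112), with Mcam, an adhesion molecule, rising by 3.96 ± 0.33, and 3 and 2 were higher with 0 lower without ADRC library a and b. The pericyte list passed without 6F library a (adjusted p = 0.0266) and with the DESeq2 test (0.035), and its median of 1.01 was 2.31 with thinned 6F libraries. Of 5 epithelial and mesothelial genes 4 were lower (camera adjusted p = 0.0535), against 1 and 0 without ADRC library a and b, and Cdh1, E-cadherin, was at least 21.9-fold lower against the 3-read floor over the 6F group, or 10.4-fold and 11.5-fold without 6F library a and b. Of 5 Schwann cell and neuron genes 1 was lower, Tubb3, a tubulin that fell by 3.10 ± 0.17 (camera adjusted p = 0.11), and the list passed without 6F library b (adjusted p = 0.028). Of 2 lymphocyte genes 1 was higher and 1 lower (camera adjusted p = 0.721). Their median was 1.43, or -0.96 with the member without ADRC reads at its bound. Of 3 erythroid genes 0 were called (camera adjusted p = 0.705). For each of these 6 lists other than the macrophage list the counts were the same when adjusted over the list alone.

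In the authors' deposited table, 421 genes had a false discovery rate under 0.05, of which 163 had a positive fold change, toward the 6F cells, and 258 a negative one. All 421 genes of the authors' deposited table were also called here, in the same direction. Both comparisons rest on the same libraries, so this overlap is no independent support. Most of the 5908 genes called here did not pass in the authors' table, among them Smpx (EDGE false discovery rate 0.536) and Birc5 (0.997). The authors' deposited table gives Myh6 a fold change of 195.9 and Myocd one of 395.1, and gives Mef2a a fold change of 3.70 with a false discovery rate of 1.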

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

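The alternatives without the 3 ribosomal-read genes, with thinned 6F libraries and with length and GC offsets were chosen after seeing the data. No paired analysis was possible because the deposited columns carry no replicate number. Pseudocounts were not tried, since the table held counts. The counts of higher and lower genes were 3038 and 2870, and leaving out a library gave 1220 to 4454 higher and 1165 to 4118 lower genes, the low ends without an ADRC library and the high ends without a 6F library, with the lone library assumed to vary like the other group. A 2-fold threshold gave 1815 lower genes. The other alternatives stayed within 1.5 times, among them DESeq2 with 2455 and 2286, thinned 6F libraries with 2816 and 2690, and length and GC offsets with 2886 and 3074. Every call shared between the main test and one of these fits had the same direction.

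With an estimated correlation the list medians stayed at 3.23 for sarcomere, 2.73 for calcium and channels, 1.36 for cardiac transcription factors, 5.98 for candidate introduced factors, 3.03 for other cardiomyocyte genes, 2.21 for smooth muscle, -4.17 for cell cycle, 1.91 for interferon and 0.99 for fatty acid oxidation, and all 9 lost their call. The estimated correlations ran from -0.052 for calcium and channels to 0.989 for candidate introduced factors. They lay below the preset 0.01 for 5 of the 9. For these 5 a higher correlation between genes cannot account for the lost call. With an estimated correlation camera also takes its degrees of freedom from the residual ones of the 4 libraries, not from the number of genes. This alone raises its p-values. The skeletal muscle median of 3.21 became -2.08 without a low-count filter and -2.22 with DESeq2, which added low-count members, was 0.24 with a mean CPM filter (10 tested), and ran from 1.23 to 3.98 over the leave-one-out fits, past the threshold at 3.98 without 6F library b. Extracellular matrix passed the threshold with DESeq2 size factors (-0.68), no filter (-0.62), a mean CPM filter (-0.68), the DESeq2 test (-0.67) and length and GC offsets (-0.80). Its median ran from -1.06 to -0.37 on leaving out a library, and the list passed in each such fit but the one without 6F library a. The DESeq2 test also called senescence (0.54), oxidative phosphorylation (0.45), glycolysis (0.67), heat shock (-0.67), immediate early (0.64), pericyte (0.98) and Wnt genes (0.74). Heat shock was called with no filter (-0.63), epithelial genes with DESeq2 size factors (-2.51) and library size alone (-2.28), Schwann cell and neuron genes with thinned libraries (-0.88), and oxidative phosphorylation was called with no filter (0.49) and with the offsets (0.48). On leaving out a library the medians ran from 0.25 to 0.60 for oxidative phosphorylation, from -0.05 to 1.14 for glycolysis and from -0.63 to -0.14 for stromal genes. The stromal list passed only without 6F library b. The cause was not tested for these.

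Of the smaller lists, brown adipocyte (2 genes, 3.76) reversed to -0.25 with no filter, -0.29 with DESeq2, -0.30 without the ribosomal-read genes, -0.28 with thinned libraries, and ran from -0.27 to 6.31 on leaving out a library. Endothelial (0.07) became -1.22 with no filter, -1.31 with DESeq2, -0.03 with offsets and ran from -0.29 to 0.27 on leaving out a library, and lymphocyte (1.43) -0.30 with DESeq2 and 0.30 to 7.52 on leaving out a library. Bone and cartilage (-1.94) was at -0.52 with no filter and -0.65 with DESeq2, and epithelial genes (-2.51) at -0.68 and -0.71. On leaving out a library, bone and cartilage ran from -2.52 to 0.18, epithelial and mesothelial from -2.56 to 3.10 (0.02 without ADRC library b), and erythroid from -4.93 to 0.33 (0.20 without ADRC library b). The cause was not tested. Of the 136 called genes selected by the rule, 0 reversed in any alternative that tested them, and 102 were past the threshold in every leave-one-out fit that tested them, whereas 34 were missed in at least 1. Of the 90 called genes named in the texts, 6 lost their call on leaving out 1 library and 36 moved by over 1.5 times. These 90 genes, which the rule had selected, thus held their calls more often than the 136 as a whole, and do not stand for all of them. Mef2c, Hopx, Tbx18, Zfpm2 and Nr2f2, named outside the rule, are not among the 90. Their calls were lost without ADRC library b. Of the 58 not called, 25 changed sign in at least 1 alternative. Acta2 was at 0.12 and Cald1 at 0.16 with scaling by library size alone, and leaving out a library gave -0.32 to 0.10 for Acta2, -0.31 to 0.17 for Cald1, -0.27 to 1.07 for Myh7 (-0.10 without 6F library b) and -0.83 to 0.13 for Gja1. ADRC depth limits the rises from few reads: 459 higher genes had 3 or fewer ADRC reads.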

Other observations

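The tests that weigh explanations for the cell cycle, macrophage and exon share patterns were chosen after the results they measure were seen, and so was the limit on how far 1 gene may move the macrophage test, with the exception of the test on short genes that are not histones. Immediate early genes, which respond within minutes to stimuli, included 9 higher and 1 lower of 17 tested (9 and 2 when adjusted over the list alone), without a call for the list (camera adjusted p = 0.189) except without 6F library a (adjusted p = 0.00523) and with the DESeq2 test (0.0245). With ADRC library a or b left out 3 were higher, and without 6F library b 9 were higher and 5 lower. Fos, Fosb and Nr4a1 rose by 4.97 ± 0.57, 5.70 ± 0.80 and 3.71 ± 0.62 (SE, n = 2) on the log2 scale, whereas Fosl1 fell by 2.46 ± 0.29. Without 6F library b these rises were 4.12, 4.85 and 2.68, without 6F library a Nr4a1 was at 4.33, and without ADRC library a or b Fosb, with 4 and 1 ADRC reads, was at 7.08 or 4.89. Ribosomal protein genes were lower in 23 of 30 with 0 higher (24 and 1 when adjusted over the list alone), with a median of -0.74 that was -0.51 with scaling by library size alone (camera adjusted p = 2.44e-05; adjusted p = 0.51 with an estimated correlation), and 7 and 4 were lower without ADRC library a and b. Rpl27 fell by 2.22 ± 0.20 and Rps2 by 1.28 ± 0.18. Of 17 heat shock and unfolded protein response genes, 3 were higher and 11 lower (3 and 12 when adjusted over the list alone, 3 and 6 with scaling by library size alone; camera adjusted p = 0.0974). Leaving out ADRC library a or b left 3 or 2 lower, and the list passed without 6F library a (adjusted p = 0.015), with no low-count filter (0.00257) and with the DESeq2 test (0.0128). Hspb1, a small heat shock protein, rose by 2.77 ± 0.28 and Asns, asparagine synthetase, fell by 2.24 ± 0.17. TGF-beta response genes were lower in 11 of 19 with 0 higher (12 and 2 when adjusted over the list alone) and a median of -0.65, or -0.42 with 8 lower and 3 higher with scaling by library size alone (camera adjusted p = 0.0193; adjusted p = 0.703 with an estimated correlation). Leaving out ADRC library a or b left 6 lower, and leaving out 6F library a or b gave 13 lower with 5 or 4 higher.

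Of 13 mitochondrial genome genes, 4 were lower and 0 higher, also when adjusted over the list alone, with a median of -0.57 (camera adjusted p = 0.0023; adjusted p = 0.694 with an estimated correlation). The call was lost without 6F library a (median -0.22, adjusted p = 0.141, 4 higher and 7 lower), and the median was -0.99 without 6F library b, with 1 higher and 10 lower. With length and GC offsets it was -0.90, with 8 lower. mt-Atp8 and mt-Nd6 fell by 4.48 ± 0.18 and 2.89 ± 0.17 on the log2 scale, while mt-Co1 stood at 4878 ± 102 and 8344 ± 2937 CPM (edgeR adjusted p = 0.0578). Of 14 Wnt pathway genes, 6 were higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.15), with 3 higher and 0 lower without 1 of the ADRC libraries, whichever was left out. The Wnt list passed without 6F library a (9 higher, 1 lower, adjusted p = 0.0063) and with the DESeq2 test (4 higher, 1 lower, 0.0406), and Sfrp1, a secreted Wnt antagonist, rose from 114.9 ± 6.31 to 1084 ± 321 CPM. Of 15 inflammatory cytokine genes, 6 were higher and 3 lower (7 and 3 when adjusted over the list alone; camera adjusted p = 0.721). Without 6F library a 10 were higher and 3 lower (median 1.68), and without 6F library b 6 were higher and 6 lower (median 0.13, camera direction down). Members included Il33, which rose by 3.83 ± 0.53, and the complement gene C3, which had 477 and 1775 reads in the 6F libraries and a log2 fold change of 4.69 without 6F library a and 2.67 without 6F library b. Of 7 bone and cartilage genes, 1 was higher and 3 lower (1 and 4 when adjusted over the list alone; camera adjusted p = 0.17), and the skeletal regulators Runx2 and Sox9 fell by 1.94 ± 0.35 and 2.04 ± 0.30, with Runx2 at -2.54 without 6F library b. Of 2 brown adipocyte genes 1 was higher (camera adjusted p = 0.753). Their median was 3.76, or 1.37 with the member without ADRC reads at its bound. Of 2 pluripotency genes 1 was lower, Myc, which fell by 2.87 ± 0.51 and stood at -2.23 and -3.98 without 6F library a and b (camera adjusted p = 0.288, or 0.0271 without 6F library b), also when adjusted over each list alone. All 6 candidate introduced factors had more CPM in 6F library a than in 6F library b, with a median log2 ratio of 1.12, against 0.23 over the 173 higher genes without an ADRC read and 0.00 over all tested genes.

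Of the tested genes, 8 of 10 replication-dependent histones and 31 of 32 cell cycle genes were lower in 6F cells. Both lists lost their call with an estimated correlation (camera adjusted p = 0.139 each). Histones are among the shortest genes tested. A loss of short transcripts from the 6F libraries does not account for the cell cycle genes, since the 30 with at least 2000 nt of exon had a median log2 fold change of -4.16 against 0.08 over all 10712 tested genes of that length. After offsets on length and GC content the cell cycle median was -4.08. For histones, 12 other protein-coding genes of at most 500 nt had a median of 0.25 (quartiles -1.51 and 1.39), with 5 higher and 5 lower. The lower ones include mt-Atp8 at -4.48. The 9 outside the mitochondrial genome had a median of 1.38, with 5 higher and 3 lower. This argues against a loss of all short transcripts. It cannot address a loss particular to histone transcripts, which was not tested. A lower share of dividing cells was not tested and stays open, as do transduction, 3 weeks of culture, sorting, RNA or library preparation and, by the labels, strain.

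Of 16 tested macrophage genes 7 were lower in 6F cells and 0 higher, and the list lost its call with an estimated correlation (camera adjusted p = 0.793). A smaller share of the same leukocytes may account for the lower genes, since sorting for GFP would remove leukocytes. Such a share would give every macrophage gene 1 fold change. The 16 tested genes ran from -4.31 to 1.84 around a common value of -2.04, with a Cochran's Q per degree of freedom of 4.50, and of 2.44 without Cd74, both over the limit of 2 set for a common fold change. An equal fold change would hold only for genes that leukocytes alone express. Which of the 16 other cells here also express was not measured, so this test cannot decide and the explanation is left open. The list's estimated correlation was 0.836, and its median was -1.35 without 6F library a and -7.01 without 6F library b. The size of the latter is uncertain, since members at or near 0 reads in 6F library a take values that depend on the prior count. The genes thus moved together between libraries, which a varying share of leukocytes would give, as could other causes. The abundant Lyz2 had 34 reads in 6F library a and 609 in 6F library b.

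Exon reads were 14.2% and 16.1% of mapped reads in the ADRC libraries against about 60% in the 6F libraries. Genomic DNA spread evenly over the genome is argued against as the whole cause: it would put a median of 40.3 reads on genes with at least 2000 nt of exon, yet 28.5% of these 17765 genes had no read in either ADRC library. The 3 genes that collect ribosomal reads held 1.48% and 1.52% of mapped reads in the ADRC libraries and 1.00% and 0.594% in the 6F libraries, which is small beside the gap in exon share. Of the exon reads, these genes held 10.5% and 9.43% in the ADRC libraries a and b and 1.66% and 0.998% in the 6F libraries. Leaving them out gave 3022 higher and 2865 lower genes. Reads in introns and ribosomal reads outside exons were not analysed here, and no biological explanation was tested for this pattern.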
